A study of Mus musculus with 2 samples.

How the data were processed

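Total RNA of glomeruli from 2 groups of male mice, wild type (WT) and podocyte-specific Sirpa knockout (Sirpa-/-), was hybridised to Agilent one-colour mouse expression arrays, 1 array per group. Per the labels' protocols, glomeruli were collected from digested renal cortex with magnetic beads, and cRNA labelled with the green dye Cy3 was made from 0.25 µg of RNA. The series design text speaks of isolated podocytes, while the sample labels and the extraction protocol speak of glomeruli; the samples are called glomerular RNA here. How many animals gave RNA to each array is not given in the sources used here.

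The deposited scanner files hold fluorescence intensity for each spot. Per the file headers, the authors extracted them with Agilent Feature Extraction 11.0.1.1, and the processed intensity is the spot signal after background subtraction and spatial detrending, with no normalization between arrays. The submitters' processing notes name Agilent Feature Extraction 9.1 instead; the disagreement could not be settled. The files also hold the median intensity of each spot and of its local background, the software's error estimate, and other values that are quality flags of 0 or 1 set by the scanner software, per the file headers. The authors' deposited value table holds log2 values for 39483 probes. Its columns shared the same median of 6.5 and 75th percentile of 9.94, as quantile normalization gives, and were not centred per gene. Each of its columns correlated best with the array of its own label, with r = 0.9945 for WT and 0.9938 for Sirpa-/- across probes, against 0.986 and 0.9864 with the other array. The steps behind the authors' log2 values are not given in the sources used here. That table served only as an alternative.

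Both arrays lay on slide 1, at positions 1 and 3. Each had 44397 spots, of which 1377 were controls and 43020 were gene spots for 39429 gene probes. A set of 399 gene probes was spotted 10 times. Well above background were 33637 gene probes (85.3%) on the WT array and 34192 (86.7%) on the array labelled Sirpa-/-, and 0 spots were saturated. The median processed signal of gene spots was 117.2 and 111.9, against 1.57 and 1.38 for negative control spots. The scanner software marked 123 and 98 gene spots as outliers.

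From the processed intensity, log2 was taken, unmarked spots of one probe were averaged, and the 75th percentile over gene probes (a signal of 1157.4 on the WT array and 1108.8 on the other) was subtracted on each array. A probe was kept when more than 50% of its spots were well above background on both arrays. Probes were named through their RefSeq accession, without version, in a gene table of the mouse assembly GRCm38.p6. The arrays were designed on an older assembly, so only names and the order of genes were taken from that table. Of 28684 probes with such an accession, 27234 matched (69.1% of all gene probes), giving 20659 genes, and 12195 probes stayed unnamed. A gene with several probes, as 5476 had, was represented by the probe with the highest mean signal over both arrays. All differences are log2 values of the array labelled Sirpa-/- minus the WT array.

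With 1 array per group there is no replicate, so no test between the conditions was made and no p-value is given. Genes were counted by a fixed size of 2-fold. The technical spread came from the probes spotted 10 times and from genes with more than 1 measured probe. For each of 35 gene lists, the median difference of the measured members was set against 10000 random lists of the same size, matched on mean signal in 20 bins. A list is said to stand apart below percentile 2.5 or above percentile 97.5 of those lists. This describes these 2 arrays only. Members of a real list vary together and random genes do not, so more real lists stand apart than chance alone would give. A list with fewer than 5 measured members got no percentile. A gene above background on 1 array only has a bound, the bright signal against the higher of the dim signal and the lowest signal well above background on that array (6.72 on the WT array and 6.21 on the other), both after scaling.

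The genes named were set by a rule written before the data were examined: Sirpa; the 12 highest and the 12 lowest differences among named genes with a mean signal above the median; the 5 highest bounds on each side; up to 4 members of each list with the largest differences; and a fixed set from the antigen presentation, T cell, podocyte and SIRP genes. A few genes that the rule names are not reported here. The lists, the thresholds and the other settings to be tried were also chosen at that point. The alternatives were quantile normalization, median centring, loess between the arrays, the authors' table, scaling on the mean log2 signal of the spike-in probes above background, no filter or a stricter filter on dim probes, the mean of a gene's probes, other fold thresholds, list means, and unmatched random lists. Background correction by normexp with an offset of 50 was run on the median spot signal, an alternative chosen after seeing the data because the mean spot signal was not among the columns.

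The counting was tested on simulated data. The WT array was set against itself plus random noise of repeated-spot size (SD 0.1 for brighter, 0.18 for dimmer probes). Among 18228 genes, 200 were given planted changes on all their probes. At 2-fold, 97.0% of changes of 1.3 and 100% of changes of 2.3 on the log2 scale were recovered, and 0 unchanged genes were counted. That noise was below the SD of 0.41 over genes between the real arrays, so 2-fold lay far outside it. This checks the counting only, not faults of single probes or differences between animals. For lists, the real differences were shuffled among genes of similar signal. Of 200 simulated lists of 20 genes with no effect, 5.0% then stood apart, which is the share the cut-offs set. Of 100 lists shifted by 0.3 on the log2 scale, 99.0% stood apart. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1 for quantile, loess and normexp.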

Results

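Gene expression was measured in glomeruli, the filtering units of the kidney, of male mice aged 8 months with experimental lupus nephritis. The disease was induced by 1 intraperitoneal injection of 0.5 ml of pristane, a hydrocarbon oil that sets off lupus-like autoimmunity, and tissue was taken 4 months later. The WT group and the group with Sirpa deleted in podocytes, the epithelial cells of the glomerular filter, had 1 array each. Sirpa encodes SIRPα, an inhibitory receptor that binds CD47. The study's title sets the question: whether podocytes that lack SIRPα present antigen to T cells more strongly, and whether the kinase SYK takes part. No uninjected mice were analysed here. Having 1 array per group, the comparison has no replicate check, and every difference is one between these 2 arrays.

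Sirpa itself was 1.55-fold higher on the array labelled Sirpa-/- (log2 difference 0.64), with a processed signal of 17320 against 11620 on the WT array. This goes against the label. The only Sirpa probe (A_55_P2118037) has no known position relative to the deleted part of the gene, and Sirpa of the other glomerular cells is left intact in a podocyte-specific knockout, so the probe may check nothing. Directions below are therefore those of the array labelled Sirpa-/- relative to the WT array, and whether that array shows loss of Sirpa is open. An exchange of the labels, which would turn every direction given here, is not excluded.

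The array labelled Sirpa-/- had higher signals for B cell genes, for haemoglobin genes, for MHC class II genes and for genes of the distal nephron, and lower signals for cell cycle genes and proximal tubule genes. The B cell list had the highest median (2.49-fold higher over 17 genes) and the cell cycle list the lowest (a log2 median of -0.71 over 28 genes). With a stricter filter on dim probes, too few B cell and distal nephron genes were left to judge those lists, and the class II list no longer stood apart, while the 4 erythroid and platelet genes left, all globins, had a median of 1.18. Podocyte, endothelial and mesangial markers lay close to 0. Among 18234 genes measured on both arrays, 284 were at least 2-fold higher and 304 at least 2-fold lower, and 17646 (96.8%) differed by less. The higher genes made up 48.3% of these, and 58.9% when the background was corrected by normexp. Across genes, which are not independent replicates, the arrays correlated with r = 0.992.

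**Figure D1:**
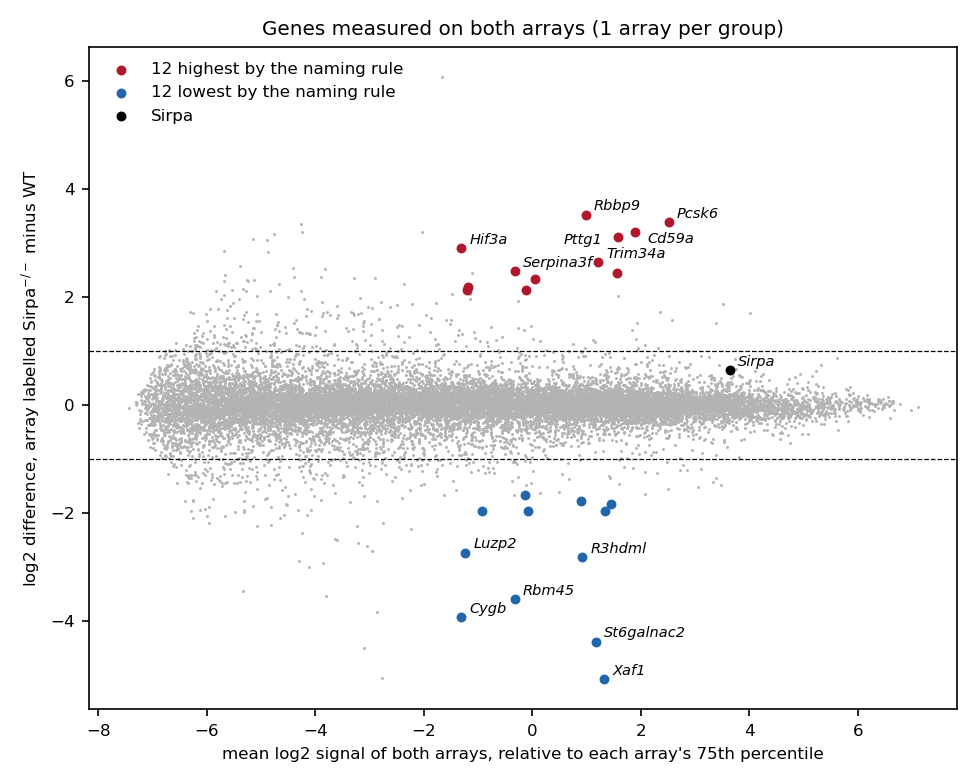
Log2 difference of each of 18234 genes (array labelled Sirpa-/- minus WT, vertical axis) against its mean log2 signal over both arrays relative to each array's 75th percentile (horizontal axis); each grey point is 1 gene, coloured points are the 12 highest and 12 lowest genes of the naming rule and Sirpa, and dashed lines mark 2-fold. Most genes lie between the lines, Rbbp9 is the highest of the coloured genes at 3.52, Xaf1 the lowest at -5.08, and Sirpa lies above 0 at 0.64.

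Among the brighter genes, Rbbp9, a serine hydrolase, was 11.49-fold higher on the array labelled Sirpa-/-, Pcsk6, a proprotein convertase, 10.39-fold, and Cd59a, which blocks the complement membrane attack complex, 9.1-fold. Pttg1 (securin, which keeps sister chromatids from separating before anaphase) was 8.55-fold higher and Hif3a, of the hypoxia-inducible factor family, 7.49-fold. The others of the 12 highest were Trim34a (6.25-fold), Serpina3f (5.59-fold), Banp (5.39-fold), the B cell lectin Cd22 (4.99-fold), Zdhhc22 (4.53-fold), the mitochondrial exonuclease Mgme1 (4.37-fold) and Clca3a2 (4.35-fold). On the other side, the interferon-inducible gene Xaf1 was 33.9-fold lower, the sialyltransferase St6galnac2 20.91-fold, cytoglobin (Cygb) 15.3-fold and the RNA-binding protein gene Rbm45 12.23-fold. St6galnac2 and Cygb lie close together on chromosome 11 in the annotated order, so they need not be independent changes. R3hdml was 7.11-fold lower and Luzp2 6.68-fold. Cdk5rap1 (3.95-fold), Ccdc68 (3.95-fold), the kallikrein gene Klk1b22 (3.93-fold), the laminin receptor subunit Itga6 (3.57-fold), Pamr1 (3.47-fold) and the cholesterol carrier Stard4 (3.17-fold) completed the 12 lowest. Klk1b22 belongs to a family of near-identical genes, so its probe may read several of them.

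Several of these genes had a further probe, and these did not all go the same way. Pttg1 (2.99 on its other probe, log2), Serpina3f (2.14), Cdk5rap1 (-1.99), Ccdc68 (-1.85) and Stard4 (-1.12) kept a difference of at least 2-fold. Rbbp9 (0.42) and Trim34a (0.39) did not, Hif3a gave 0.67 and -0.03, and Banp gave -0.04. Xaf1 gave 5.25 on its other probe, the opposite direction, so no direction can be given for this gene. Of 41 genes at least 2-fold higher with a second measured probe, 19 (46.3%) were at least 1.5-fold higher on it, against 4.8% of other genes. Of 62 at least 2-fold lower, 23 (37.1%) were at least 1.5-fold lower on it, against 4.0% of other genes. On the second probe, 5 of the 41 higher genes and 20 of the 62 lower genes went the opposite way or lay at 0. Single spots of 360 probes spotted 10 times gave log2 differences with a median SD of 0.12, which is technical spread alone and was 0.18 for the 190 dimmer probes.

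The MHC class II genes, which present peptides to CD4 T cells, were higher as a group on the array labelled Sirpa-/-. Of 18 measured members, 6 were at least 2-fold higher and 0 at least 2-fold lower, and the median of 0.33 lay above all 10000 matched random lists. With the stricter filter on dim probes the median was 0.12 over 9 genes (percentile 96.01), which did not stand apart. The genes of the classical class II molecules were higher at 2.76-fold for H2-Aa, 2.25-fold for H2-Eb1 and 1.89-fold for H2-Ab1, which gave 1.0 (log2) on its other probe, and the invariant chain Cd74 was 2.44-fold higher. H2-DMb2 (3.18-fold) and H2-Oa (2.63-fold), which act in peptide loading, were also higher, H2-DMb2 from a signal of only 10.06. Ciita, the master regulator of class II transcription, had a log2 difference of 0.0 at dim signals of 33.58 and 32.25. Without H2-Oa, H2-Ob and H2-DMb2 the median of the other 15 members was 0.12, at percentile 97.18, and without H2 genes and Cd74 it was 0.02. B cell markers moved with this list, at a median of 1.32, and so did dendritic cell markers, at 0.22.

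MHC class I genes shifted less. Of 20 members 0 reached 2-fold, the median was 0.1 (percentile 99.17), the mean of 0.04 did not stand apart, and the largest differences were -0.6 for H2-Q1 and -0.57 for the chaperone calreticulin (Calr), with 0.41 for the peptide transporter Tap1 and 0.34 for Nlrc5. The costimulatory and coinhibitory ligands, which set the T cell's second signal, had a median of -0.08 over 17 genes (percentile 12.48). Cd80 (-0.13), Cd86 (-0.44) and Cd40 (-0.67) were lower or near 0, Vcam1 was 2.49-fold lower and Icam1 2.08-fold higher on the array labelled Sirpa-/-.

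Syk differed by 0.12 (log2), 1.09-fold. The list of SYK and ITAM signalling genes had a median of 0.12 over 28 genes, at percentile 98.53, and a mean of 0.01. It stood apart in only 7 of 11 alternatives, and with the stricter filter on dim probes its median was 0.02 over 12 genes (percentile 55.51). Only 1 member reached 2-fold: Blnk, the adaptor of the B cell receptor, was 2.78-fold higher. Src (-0.96), Clec4e (-0.74) and Vav2 (0.7) followed, Src and Vav2 at dim signals. RNA levels do not show the phosphorylation state of SYK. In the SIRP, CD47 and SHP phosphatase list, 0 of 11 genes reached 2-fold and the median was 0.2 (percentile 99.63), while the mean of 0.11 did not stand apart. Beside Sirpa, the values were 0.37 for Sirpb1a, 0.34 for Cd47, 0.27 for Sftpd, 0.25 for Skap2 and 0.2 for Sirpb1b. Ptpn6 and Ptpn11, the phosphatases SHP-1 and SHP-2 that SIRPα recruits, each gave -0.1, Ptk2b and Thbs1 each -0.07, and Fyb -0.47.

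Among leukocyte lists, B cell and plasma cell markers stood out: 9 of 17 genes were at least 2-fold higher on the array labelled Sirpa-/- and all 17 lay above 0, though only Cd22 passed the stricter filter on dim probes. Besides Cd22, the IgM receptor Fcmr was 3.71-fold higher, the B cell receptor subunit Cd79b 3.66-fold and Ms4a1 (CD20) 3.53-fold. T cell markers had a smaller shift, with a median of 0.27 over 20 genes (percentile 99.98) and 0 genes at 2-fold, and 4 genes with a median of 0.1 were left by the stricter filter. Cd2 gave 0.89 (0.32 on its other probe), Cd3g 0.85, Il7r 0.84 and Cd3d 0.69, and the values were 0.3 for Cd3e, 0.43 for Cd8a and 0.09 for Cd4. T cell effector, helper and regulatory genes did not stand apart, with a median of 0.05 over 22 genes (percentile 79.17). Of these, Cxcr5, a receptor of follicular T cells and of B cells, was 2.48-fold higher and Ifng gave 0.84, both at dim signals.

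Dendritic cell markers had a median of 0.22 over 13 genes (percentile 99.66), led by Cd209a (2.7-fold higher) and Clec10a (2.09-fold), but the list did not stand apart with normexp, at 0.17. Macrophage and monocyte markers lay on the other side, at -0.15 over 20 genes (percentile 0.7), a direction that turned to 0.02 with normexp. Adgre1 (F4/80) gave -0.91 and -0.73 on its other probe, and Cx3cr1 -0.71 but only -0.09 on its other probe. Neutrophil markers had a median of 0.17 over 16 genes (percentile 99.46), with Mmp8 2.1-fold higher at dim signals and Ltf at -0.91, and the list's mean of 0.13 did not stand apart. Erythroid and platelet genes were higher at a median of 0.88 over 12 genes, above all 10000 random lists. The haem synthesis gene Alas2 was 3.06-fold higher, and the globin genes Hbb-bt (3.23-fold), Hba-a1 (2.84-fold) and Hbb-bs (2.83-fold) were too, though globin genes are near-identical copies whose probes may cross-read. Blood cell markers thus moved with the B cell and class II lists.

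**Figure D2:**
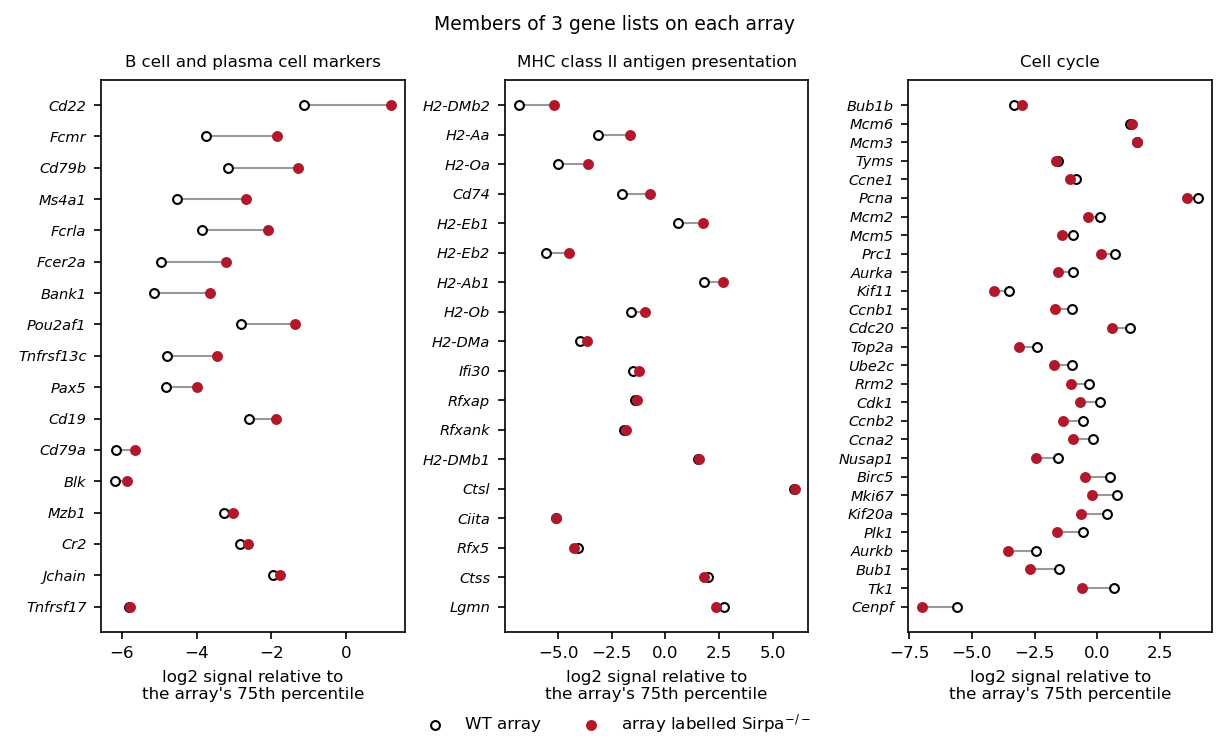
Log2 signal relative to each array's 75th percentile (horizontal axis) of each measured member of 3 gene lists on the WT array (open points) and the array labelled Sirpa-/- (red points), joined by a line, with 1 array per group. In the B cell list all 17 genes lie higher on the array labelled Sirpa-/-, in the MHC class II list 15 of 18 lie above 0 in difference, and in the cell cycle list 26 of 28 lie lower, a direction that held under all 11 alternatives for the list median.

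Markers of the glomerular cells differed little. Podocyte markers had a median of -0.03 over 32 genes (percentile 33.02). Synpo gave -0.07, Wt1 0.28 and nephrin (Nphs1) 0.63, while Kirrel2 was 2.08-fold lower on the array labelled Sirpa-/-, Dag1 gave -0.75 and Nes -0.55. Endothelial markers had a median of -0.04 over 24 genes (percentile 26.71), with Gpihbp1 at 0.65 and Plvap at 0.64. Mesangial, smooth muscle and renin cell markers lay at -0.06 over 19 genes (percentile 13.65), with Myh11 2.19-fold higher at dim signals and Itga8 at -0.42. With the stricter filter that list lay at -0.11 (percentile 2.09) and stood apart. Parietal epithelial markers lay at 0.12 over 9 genes (percentile 90.25), with Pax8 at -0.68 and Krt18 at 0.54.

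The proximal and distal tubule lists moved apart. Markers of the loop, distal tubule and collecting duct had a median of 0.31 over 22 genes (percentile 99.99), of which the stricter filter left 4 with a median of 0.17, and 4 were at least 2-fold higher on the array labelled Sirpa-/-. These were the thiazide-sensitive cotransporter Slc12a3 (5.77-fold), calbindin (Calb1, 2.63-fold), the potassium channel Kcnj1 (2.6-fold) and the magnesium channel Trpm6 (2.05-fold). Slc12a3 and Calb1 rose from dim WT signals of 22.58 and 26.62. Of the 22 genes 18 lay above 0, but markers of the same segment did not all share the shift. Of the loop markers, Slc12a1 gave -0.15 and Umod 0.97. Of the collecting duct markers, Aqp2 (0.15), Aqp3 (0.05) and Fxyd4 (-0.08) lay near 0. Foxi1 and Scnn1b, also of the collecting duct, each gave 0.91, Scnn1b at dim signals. Egf (0.03), the brightest gene of the list, and Pvalb (0.19) differed little. Proximal tubule markers had a median of -0.24 over 25 genes (percentile 0.01), with 21 below 0 and 0 at 2-fold. The water channel Aqp1 gave -0.93, Slc5a12 -0.8, Slc7a13 -0.67 and Slc17a3 -0.58.

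**Figure D3:**
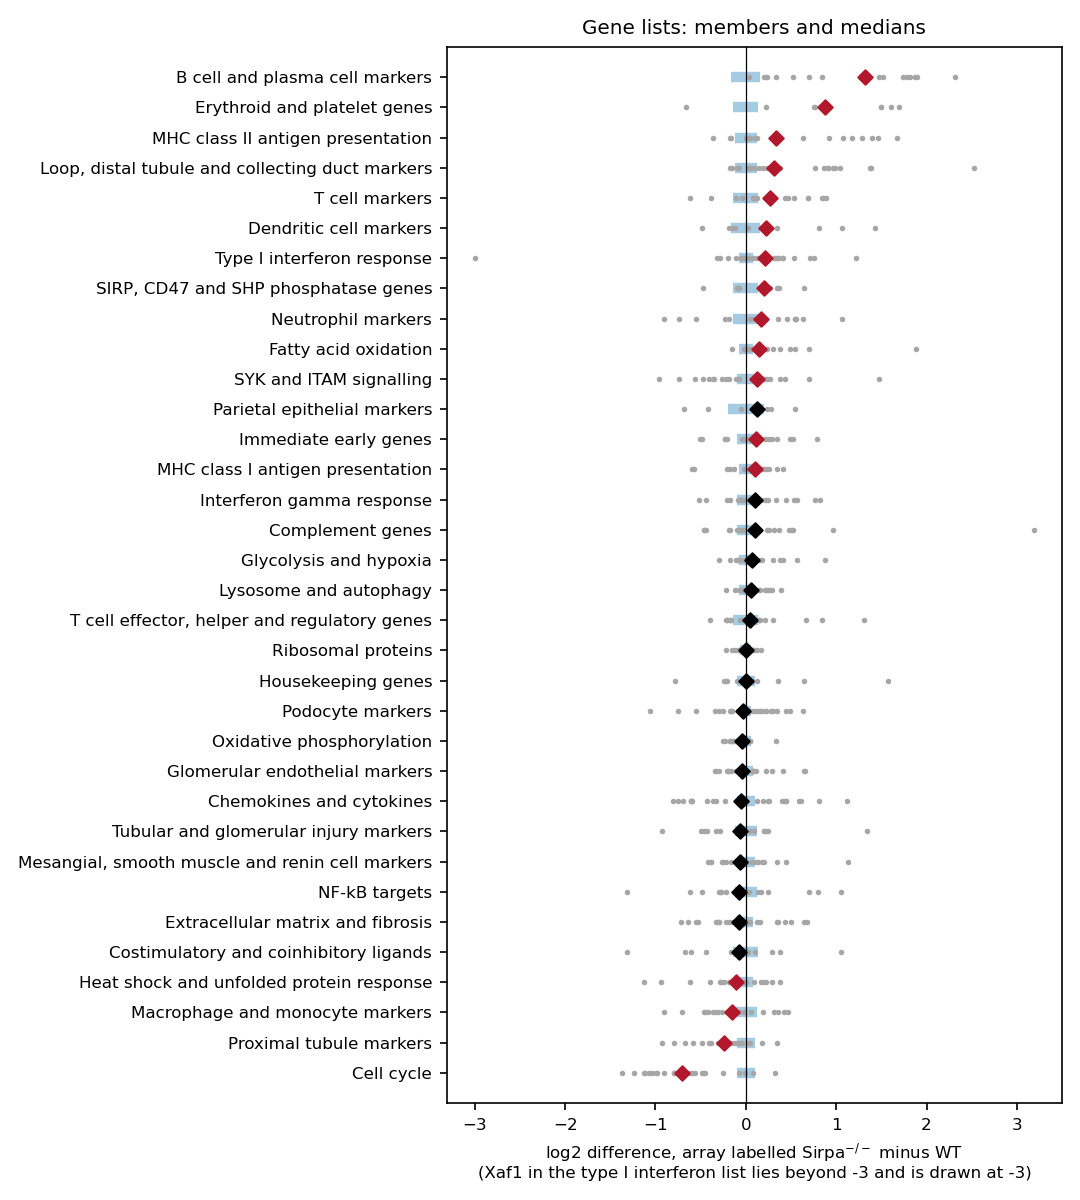
Log2 difference (array labelled Sirpa-/- minus WT, horizontal axis) of each measured member (grey points) and the median (diamond) of the 34 gene lists with a percentile, 1 per line. Red diamonds stand apart from matched random lists (17 lists) and black ones do not; the blue bar spans 2 SD of the random lists' medians to either side of 0. The B cell list lies highest at 1.32 and the cell cycle list lowest at -0.71.

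Cell cycle genes were lower on the array labelled Sirpa-/-, with 26 of 28 below 0, 6 at least 2-fold lower and 0 higher, below all 10000 random lists. Cenpf was 2.58-fold lower at dim signals (23.65 on the WT array and 8.782 on the other), the thymidine kinase Tk1 2.36-fold, the spindle checkpoint kinase Bub1 2.19-fold and Aurkb 2.17-fold. Pttg1, which acts in the same process and was 8.55-fold higher, is not on the list. Heat shock and unfolded protein response genes had a median of -0.11 over 21 genes (percentile 1.64), with the endoplasmic reticulum genes Sdf2l1 2.19-fold lower and Pdia4 at -0.94. With normexp that median was -0.04 and did not stand apart.

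Interferon-responsive genes differed modestly. The type I interferon list had a median of 0.21 over 28 genes, above all 10000 random lists, and a mean of 0.03 that Xaf1 pulls down and that did not stand apart. Oas2 was 2.33-fold higher on the array labelled Sirpa-/-, Ifi44 gave 0.76 and Zbp1 0.71. The interferon gamma list had a median of 0.1 over 21 genes (percentile 97.17), with Irgm2 at 0.82, Ubd at 0.77 and Tgtp1 at 0.57. Chemokines and cytokines lay at -0.05 over 30 genes (percentile 15.82), where the alarmin Il33 was 2.17-fold higher, Ccl5 gave 0.81 and the B cell chemokine Cxcl13 -0.75. NF-kB targets lay at -0.07 over 20 genes (percentile 9.91), with Birc3 at 0.8 and Nfkbiz at 0.7, and at -0.17 with the stricter filter (percentile 0.76), where they stood apart. Complement genes lay at 0.1 over 23 genes (percentile 96.6), where Cfb gave 0.97 beside the high value of Cd59a. That list stood apart with the stricter filter, at 0.24 (percentile 99.96). Immediate early genes had a median of 0.11 over 22 genes (percentile 99.16), with Egr2 at 0.79 and Nr4a1 at -0.51, and 0.07 with the stricter filter (percentile 91.51), which did not stand apart.

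Metabolic lists showed fatty acid oxidation genes slightly higher on the array labelled Sirpa-/-, at a median of 0.15 over 23 genes (percentile 99.95), with 21 above 0. Pdk4, which restrains glucose oxidation, gave 0.7. Oxidative phosphorylation genes lay at -0.04 over 30 genes (percentile 23.87), with Uqcrb at -0.25. Glycolysis and hypoxia genes lay at 0.07 over 22 genes (percentile 96.13), with Bnip3 at 0.88 and Pdk1 at 0.57, and lysosome and autophagy genes at 0.06 over 28 genes (percentile 96.78), with Sqstm1 at 0.39. Extracellular matrix genes lay at -0.07 over 29 genes (percentile 5.83), with Col8a1 at -0.72 and Col1a1 at 0.68. Injury markers lay at -0.06 over 15 genes (percentile 16.91), where osteopontin (Spp1) was 2.53-fold higher and Trpc6, a podocyte ion channel, gave -0.93. Ribosomal protein genes had a median of 0.0 over 30 genes (percentile 81.84). Housekeeping genes also lay at 0.0, over 14 genes (percentile 63.4), though the transferrin receptor Tfrc was 2.97-fold higher and Actb gave -0.78. Of the sex chromosome genes, 4 were measured, with Ddx3y at -0.13 and Xist at 0.22 at a dim signal. In all, 17 of 34 lists stood apart, 13 above and 4 below.

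Genes well above background on 1 array only have bounds in place of folds. On the array labelled Sirpa-/- alone there were 435 such genes, of which 101 were at least 2-fold higher by their bound. Cfap43 was at least 19.0-fold higher, Dhrs9 at least 12.2-fold, the mast cell and basophil IgE receptor subunit Ms4a2 at least 10.2-fold, the vomeronasal receptor gene Vmn1r122 at least 9.69-fold and Lce1l at least 7.92-fold. On the WT array alone there were 270, of which 64 passed 2-fold by their bound. There, Fn3krp was at least 14.9-fold lower on the array labelled Sirpa-/-, Spint4 at least 13.5-fold, Crb1 at least 10.2-fold, Vxn at least 10.1-fold and Chst5 at least 9.49-fold. A further 1708 named genes were not well above background on either array.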

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

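No paired analysis was possible because each group had 1 array, and for the same reason no array was left out in turn. Normexp on the mean spot signal was not run for lack of that column. Normexp on the median spot signal, and the shortened class II lists, were chosen after seeing the data, as was the way the spike-in probes were combined.

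Sirpa kept its direction in all 9 alternatives that gave it a value, from 0.63 to 0.74. With only 1 probe, a bright one, its value could not change with the filters on dim probes or the mean of a gene's probes. Quantile normalization, median centring, loess and the authors' table moved none of the counts of genes by more than 1.5 times, and of the genes counted as lower each of them kept all 304. Scaling on the 5 of 10 spike-in probes well above background on both arrays gave 322 higher and 272 lower. It raised every difference by a constant, with an all-gene median of 0.05 and medians of 0.15 for class I and 0.02 for podocyte markers. This moves the random lists alike and could change no list's call. At signals of at most 27.6 and 25.7, these 5 probes differed by -0.32 to 0.15. Spike-in RNA may be absent, and then this scaling checks nothing. Median centring likewise could change no call, and the authors' table looked quantile-normalized already. The counts that follow therefore hold fewer separate checks than alternatives. The cell cycle, proximal tubule and fatty acid oxidation lists stood apart in 11 of 11 alternatives. B cell, erythroid, distal nephron, T cell, neutrophil, SIRP and type I interferon lists did in 10 of 11. Dendritic cell, class I, immediate early and heat shock lists did in 9, macrophage markers in 8 and SYK and ITAM signalling in 7. Class II did in 10 of 13, which include the shortened class II lists, where the call was lost. Among the alternatives run on every list, class II lost it only with the stricter filter. Complement genes gained that call with quantile normalization (0.12), loess (0.11), normexp (0.18), the authors' table (0.12), the stricter filter (0.24) and the list mean (0.25). Mesangial markers (-0.11) and NF-kB targets (-0.17) gained it with the stricter filter, and glycolysis genes (0.1) with the mean of a gene's probes.

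With normexp, which adds an offset of 50 and so shrinks the differences of dim genes, 113 genes were higher and 79 lower. The medians became 0.78 for B cell markers, 0.79 for erythroid and platelet genes, -0.56 for the cell cycle, -0.16 for proximal tubule markers, 0.09 for costimulatory ligands and 0.02 for macrophage markers, which turned their direction. Without a filter on dim probes, 670 genes were higher and 613 lower. The stricter filter left 44 higher and 60 lower among 9688 genes. It left 1 B cell gene (2.32), 4 erythroid or platelet genes (median 1.18), 4 distal nephron genes (0.17) and 4 T cell genes (0.1), too few for a percentile. The class II median was 0.12 over 9 genes and that of SYK and ITAM signalling 0.02 over 12, and neither stood apart. Apart from the erythroid and platelet list, whose brighter genes had the higher median, these lists therefore rest largely on dim probes.

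At a 1.5-fold threshold 790 genes were higher and 962 lower, and at 3-fold 98 and 73. With the mean of a gene's probes, Xaf1 turned to 0.08, since its probes oppose each other, and the medians were 1.01 for B cell, 0.57 for distal nephron and -0.17 for proximal tubule markers. With list means, 11 lists stood apart. The means were 1.11 for B cell markers, 0.57 for distal nephron markers and 0.55 for class II. The means of 0.04 for class I and 0.01 for SYK and ITAM signalling no longer stood apart. The class II median was 0.12 without H2-Oa, H2-Ob and H2-DMb2 and 0.02 without H2 genes and Cd74, and it stood apart in neither case. Apart from these effects of construction, the cause was not tested.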

Other observations

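Fkbp5, a chaperone gene strongly induced by glucocorticoids and singled out after its value was seen, had a log2 difference of 1.86 on the array labelled Sirpa-/-, and Hif3a, also a glucocorticoid target, 2.9 on its brightest probe but 0.67 and -0.03 on its other probes. A list of 24 other glucocorticoid-induced genes, written before their values were looked at as a group, had a median of 0.34, above all 10000 matched random lists, and 21 of its genes lay above 0. Tsc22d3 (GILZ) gave 0.57, Sult1a1 0.9, Angptl4 0.96, Cebpd 0.54 and Mt1 0.53, while Sgk1 (0.07), Per1 (0.01), Zbtb16 (-0.04) and Dusp1 (-0.04) lay near 0. Of these genes, Lcn2, Dusp1 and Nfkbia are also on other lists. A stronger glucocorticoid response in the animal or animals behind that array is a candidate explanation, as a hypothesis from 2 arrays. Clock output genes minus genes of the opposite phase gave a difference of 0.19, too close to its bound to decide on another time of day at collection.

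Among probes with no gene name, 9265 were measured on both arrays, and 156 were at least 2-fold higher and 246 at least 2-fold lower on the array labelled Sirpa-/-. The largest difference of any named gene was that of Trim12a, at 6.07, with 4.57 on its other probe; it was dimmer than the naming rule asks and is named after its value was seen.

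The tests of gene order along chromosomes, of macrophages, of interferon gamma and of the glomerular share below were chosen after the values they use had been seen. The other tests were prompted by patterns already seen, but the values they use had not been looked at for that purpose. The condition that a value pass its bound by more than its spread was added after the first results, and it left the clock, the interferon gamma and the second-probe comparisons undecided.

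The genes that differed over 4-fold, 47 higher and 32 lower, may in part mark DNA of another mouse strain rather than loss of Sirpa. Of these 79 genes, 7 (Exd1, Jmjd7, Patl2, Prom2, Tmc2, Mgme1 and Rbbp9) lay within 200 measured genes of Sirpa in the annotated order. Random draws, not matched on signal, gave a median of 2, 5 at the upper percentile used for lists, and 8 at most. DNA carried along with a targeted gene would give such an excess. Rbbp9, however, gave only 0.42 on its other probe. Elsewhere, 17 of 72 had another such gene within 20 measured genes (random median 10, upper percentile 19), which leaves it open there. Among the 17 were the neighbours Cygb (-3.94), Prcd (-3.84) and St6galnac2 (-4.39) on chromosome 11. Trim34a (2.64) and Trim12a (6.07), adjacent on chromosome 7, were too. Such neighbours need not be independent changes. Of the 79 genes, 19 had another measured probe. On it, 8 (42.1%, exact 95% binomial interval 20.3 to 66.5) differed at least 2-fold the same way and Neb and Xaf1 the opposite way. This leaves sequence variants under single probes open. Spots of the 79 genes lay a median of 168.8 µm from the nearest other such spot. Random draws gave a median of 155.1 µm, and 127.4 µm at the lower percentile used for lists. The spots were thus no closer together than random ones. This gives no sign of a local defect of the array surface behind most of them. A median cannot show a defect under a minority of the spots, so that stays open. The strain background is not given in the sources used here, and an effect of Sirpa loss on these genes stays open and untested.

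For the higher MHC class II signal, more macrophages are argued against only weakly. Their markers had a median of -0.15 with an SD over members of 0.37, below the class II median of 0.33. That SD is too wide to set against the class II median of 0.12 without H2-Oa, H2-Ob and H2-DMb2. The macrophage median was 0.02 with normexp and -0.1 without a filter on dim probes, and stood apart in neither case. An SD over members is a spread of single genes, not an error of the median. By the same measure, a stronger interferon gamma response stays open. Its list had a median of 0.1 with an SD over members of 0.35, wider than its gap to the class II median of 0.33. More B cells, which carry class II, may account for part of it: a second B cell list of 21 genes that are on no other list had a median of 0.35, above all 10000 random lists but under the 0.5 asked for in advance, so it cannot be told apart from a smaller shift. Its brightest gene, Cd200, which other cell types also express, gave -0.21 and the B cell factor Ebf1 -1.26, while Btla (2.23), Ly6d (1.66), Spib (1.4) and Vpreb3 (1.31) were higher at dim signals, and 4 members were at least 2-fold higher and 1 lower. Dendritic cells, whose markers lay at 0.22, and a change of class II in podocytes after Sirpa loss, which the study's title points to, stay open, as RNA of whole glomeruli does not separate the cell types.

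For the higher distal and lower proximal tubule markers, a lower share of glomeruli on the array labelled Sirpa-/- is argued against, since it would raise both, and the medians lay 0.55 apart against an SD of 0.08 for random lists. Another mix of tubule segments carried along with the glomeruli is a candidate explanation: a second distal list of 21 genes had a median of 0.61, above all 10000 random lists, with Cldn8 at 1.98, Tmem213 at 1.37, Wfdc2 at 1.08 and Fxyd2 at 0.61, though only 14 of its genes lay above 0 and the others below, among them Slc16a7 at -1.28, Irx2 at -0.56 and the abundant Stk39 at -0.99. Magnetic collection of glomeruli would remove most tubules. An effect of the genotype on tubule gene expression stays open and untested.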
